A study of Homo sapiens with 6 samples.

How the data were processed

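Total RNA of MRC5VA cells, a line of human lung fibroblasts transformed with the SV40 virus, was extracted with a column kit, and mRNA libraries were sequenced as paired-end reads of 72 bp on a Genome Analyzer IIX, per the labels' protocols. The labels place the 6 libraries in 3 groups of 2 biological replicates. These are untreated cells, cells 8 h after 15 J/m2 of UVC light (a short-wave ultraviolet that leaves bulky lesions in DNA), and cells 24 h after the same dose. Nothing in the labels says that the replicates came from separate days, and p-values measure the spread between these libraries.

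The authors deposited a table of raw read counts per gene symbol for all 6 libraries, and, for each UVC library, tables of splicing events. TopHat2 2.0.8 and the builds hg19 and GRCh37 are named in the submitters' processing notes. The read counter, the gene annotation and whether counting used strand are not given in the sources used here. Without strand, reads of a gene and of an overlapping gene on the other strand fall together, and reads of near-identical copies may have been split or dropped. The deposited splicing tables have the layout of MISO, whose version and event annotation are not given in the sources used here. Per the file headers they hold, for each event and a pair of libraries, the fraction of the event's transcripts that carry the first-listed isoform (0 to 1) with its interval. They also hold a Bayes factor, which is the ratio of the evidence for a difference to that for none, per the file headers. Every listed event has a Bayes factor of at least 10 and at least 20 reads, so events without a difference are not listed.

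The header of a splicing table does not name its libraries. The second library of each event had the same reads in the 8 h and 24 h tables of one replicate number, in 671 of 671 shared events for replicate 1 and 377 of 377 for replicate 2, and is called the reference. The ratio of first to second library reads across events correlated with the ratio of gene counts, UVC library to untreated library of the same number, with a Spearman rank correlation across genes of 0.869 to 0.916. The first library was therefore read as the table's own UVC library and the reference as the untreated one.

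The count table held 16973 genes, and none of its columns belonged to another sample. Of its symbols, 13816 were matched to the GENCODE annotation of the GRCh37 build by symbol and 1081 by an older symbol, 14897 in all, and 2076 were not matched. The table has 22 entries whose symbol a spreadsheet had turned into a date, which were left unnamed. Coordinates of genes are from that annotation, counted from 1, and coordinates of splicing events are those of the deposited tables, on hg19.

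Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its default settings, which left 14166 genes and dropped 0.0326% of the counts. Libraries were scaled with TMM factors. A rise or fall is thus relative to the other transcripts of a library, and no measure of total mRNA per cell was used. One quasi-likelihood model with a term per group was fitted to all 6 libraries (glmQLFit), and 3 contrasts were tested two-sided with glmQLFTest: 8 h against untreated, 24 h against untreated, and 24 h against 8 h. The last is the test of the difference between the 2 recovery times. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The square root of the common dispersion, the biological coefficient of variation, was 0.248. Log2 fold changes are given with their standard error (SE), and levels as counts scaled to the mean effective library size, as mean ± SD of 2 libraries. Intervals on counts cover counting error only.

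The model was tested on simulated counts with the untreated means, the library sizes and the spread of these data, changed at 8 h in 4 sets of 50 genes among 13745. At 8 h it called 14 of 50 genes raised 2-fold, 4 of 50 lowered 2-fold, 49 of 50 raised 4-fold and 47 of 50 lowered 4-fold, and 8 of 13545 unchanged genes. In this simulation, with 2 libraries per group, most 2-fold changes were thus missed. It changed far fewer genes than the 2909 called at 8 h in the data, and held no shared effect of the replicate number. The adjusted p depends on how many genes change, so these shares may not hold for the data.

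The labels number the replicates 1 and 2 in each group. Deviations from the group means of same-numbered libraries correlated across genes with r of 0.485 between untreated and 8 h, 0.399 between untreated and 24 h and 0.302 between 8 h and 24 h, and the third principal component (13.2% of the variance) separated the numbers in all 3 groups. Since each correlation lay above 0.1, the numbers were taken to pair the libraries, although the labels name no shared day or batch. The calls given first are those of the model without a block, which was fixed before the data were examined. A model with the replicate number as a block was fitted beside it. Values with the block are given where the call differs or a count moves by more than 1.5 times.

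Before the data were examined, 21 gene lists, the tests, the alternative settings and the rule for naming genes were fixed. Of the lists, 20 had at least 5 tested members. The list of 13 mitochondrially encoded genes had 0 in the table and was not analysed here. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, which compares a list with all other genes. Beside it stand camera with a correlation estimated per list, and fry, which tests whether the genes of a list move on balance one way. For 8 h and 24 h against untreated, the 12 largest rises and 12 largest falls were named among changed genes with a mean of at least 50 scaled counts in a group and no overlap between the groups' libraries, and 6 each for 24 h against 8 h. From each list up to 4 members with the smallest p were named, and ASCC3 always, as the gene the study is known for. Members that moved against the rest of their list and other small counts are also named, after their values were seen. Some genes that meet these rules are not reported here, and stay in the counts.

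The relation of the change to gene length was measured as Spearman's rank correlation across 12867 genes with a known genomic span, from the first to the last annotated base. Genes are not independent replicates, so no p is given for it. A splicing event was counted as changed where both replicates had a Bayes factor of at least 10 and a change in the fraction of at least 0.2 of the same sign. The direction of alternative first and last exons was tested across events with a two-sided exact binomial test. Events on alternate haplotype sequences repeat events of the primary chromosomes, and the count without them was added after the data were seen. In 20 draws, all 6 libraries were simulated around each gene's mean over all groups, with no gene changed. Overlaps between the 2 UVC comparisons, which share their untreated libraries, were set beside these draws. After the data were seen, they were also counted with 1 untreated library for each comparison, both ways, in a model that takes the spread from the 8 h and 24 h groups.

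Alternatives to the main settings were DESeq2 1.42.0 size factors and its Wald test, scaling by total counts, other count filters, a fit of the 4 libraries compared, stricter thresholds, the replicate block, and leaving out each library in turn, where a group of 1 library is assumed to vary like the others. Splicing tables, neighbouring genes and figures were handled in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.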

Results

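The data were gene counts and splicing events of 6 mRNA libraries of MRC5VA fibroblasts, 2 each from untreated cells, cells 8 h after UVC and cells 24 h after UVC. Total counts were 21234419 and 24451060 in the untreated libraries, 25206882 and 26368934 at 8 h, and 21871523 and 27389295 at 24 h. Log2 CPM (counts scaled to library size) of the 2 libraries of a group correlated across genes with r of 0.979, 0.975 and 0.976. Replicates differed by far more than counting noise (chi-square per degree of freedom 48.7, 107 and 61.8), so no library was a copy of another. The first and second principal components held 47.8% and 29.9% of the variance. Reads assigned to the 5.8S ribosomal RNA gene RNA5-8S5, which an mRNA library should hold few of, made up 0.481% and 1.22% of the untreated libraries, 1.14% and 3.41% at 8 h, and 0.595% and 1.48% at 24 h, with the higher share in replicate 2 of each group.

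The first comparison asked which transcripts differed 8 h after irradiation. ATF3, a stress-induced transcription factor, rose from 689 ± 98.4 to 3691 ± 535 scaled counts (SD, n = 2). CCNE1, the cyclin E1 gene of S phase entry, rose from 95.4 ± 14.9 to 953 ± 62.6, and PMAIP1, which encodes the pro-apoptotic protein NOXA, from 906 ± 146 to 6929 ± 1705. Of 78 ribosomal protein genes 43 rose, of 48 oxidative phosphorylation genes 21 rose, and of 41 mitotic genes 16 fell and 1 rose (list adjusted p = 0.632, 0.632 and 0.729 with an estimated correlation). The 12 named falls were in genes spanning 112 to 910 kb. In edgeR's quasi-likelihood test, 2909 of 14166 genes changed at an adjusted p under 0.05, of which 1161 rose and 1748 fell, 819 and 1590 of them by at least 2-fold. With the replicate number as a block, 5988 genes changed (2997 rose, 2991 fell), and these held all 2909. Without the library of untreated replicate 1 the count was 1566. Scaling by total counts alone called 3031 genes, of which 22.5% rose against 39.9% with TMM, and moved the median log2 fold change of all genes from 0.06 to -0.13.

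Among 32 immediate early and AP-1 genes tested, 13 rose and 2 fell (14 and 2 adjusted over the list alone; list adjusted p = 1.8e-04, and adjusted p = 0.632 with an estimated correlation). ATF3 rose by 2.42 ± 0.27 (log2, SE; adjusted p = 0.0013), DUSP6, a phosphatase of the ERK kinase, by 2.52 ± 0.29, FOS by 3.10 ± 0.50 and MAFF by 1.96 ± 0.32. CYR61, a secreted matrix protein, and DUSP10, a phosphatase of stress kinases, fell, with log2 changes of -1.03 and -1.13. Of 16 replication-dependent histone genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 1.43e-07, and adjusted p = 0.632 with an estimated correlation), among them HIST1H3A at 2.36 ± 0.33 and HIST2H2BE at 2.21 ± 0.37. These transcripts mostly lack a poly(A) tail, and histone genes are near-identical copies whose reads may be split. The share of RNA5-8S5, which has no poly(A) tail either, was also higher at 8 h than in the untreated library of the same number, 1.14% against 0.481% and 3.41% against 1.22%. Of 41 genes of the G1/S transition and DNA replication, 13 rose and 2 fell (14 and 2 adjusted over the list alone, 21 and 3 with the block; adjusted p = 0.00292, and adjusted p = 0.729 with an estimated correlation). CCNE1 rose by 3.32 ± 0.33, PCNA, the sliding clamp of DNA polymerases, by 0.99 ± 0.21, and SLBP, which binds histone mRNA, by 1.16 ± 0.26. PRIM2, a primase subunit, and GINS1, a part of the replicative helicase, fell, with log2 changes of -1.05 and -0.92. That list lost its call without the library of 8 h replicate 1 (adjusted p = 0.0611). Of 41 genes of G2/M and mitosis, 16 fell and 1 rose (19 and 1 adjusted over the list alone, 24 and 2 with the block; adjusted p = 4.6e-04, and adjusted p = 0.729 with an estimated correlation). BUB1B, of the spindle checkpoint, changed by -1.22 ± 0.24, AURKA, a mitotic kinase, by -1.20 ± 0.25 and KIF14 by -1.35 ± 0.31, whereas BIRC5, the survivin gene, rose by 0.79.

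Cytosolic ribosomal protein genes moved one way: 43 of 78 rose and 0 fell (74 and 0 adjusted over the list alone, 75 and 0 with the block; adjusted p = 1.98e-14, and adjusted p = 0.632 with an estimated correlation). RPL9 rose by 0.90 ± 0.16 and RPL15 by 0.83 ± 0.16, and the median span of the list was 5.44 kb. Many of these genes have processed pseudogenes whose reads may be shared. All tested genes under 10 kb had a median log2 change of 0.61 at 8 h, with quartiles of 0.24 and 0.95. The median of the ribosomal list, 0.83, and that of the oxidative phosphorylation list, 0.78, lay within that range. The list test sets a list against all other genes, including the long ones that fell. It therefore does not separate either list from other short genes. The 8 h medians of other lists also lay within the quartiles of all genes in the bin of their median span. These were immediate early genes (0.91, under 10 kb), G1/S genes (0.50) and general transcription genes (0.44, both 10 to 30 kb, quartiles -0.04 and 0.67). The G2/M median was -0.56 (30 to 100 kb, quartiles -0.68 and 0.20). The test does not separate these lists from other genes of like span either. Of 48 nuclear genes of oxidative phosphorylation, with a median span of 8.31 kb, 21 rose and 0 fell (34 and 0 adjusted over the list alone, 45 and 0 with the block; adjusted p = 5.32e-10, and adjusted p = 0.632 with an estimated correlation), for instance NDUFA1 at 1.00 ± 0.26. Of 45 genes of general transcription and elongation, 10 rose and 4 fell (11 and 4 adjusted over the list alone, 21 and 7 with the block; adjusted p = 0.0274, and adjusted p = 0.729 with an estimated correlation). HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose by 2.48 ± 0.25, CCNT1, the cyclin of that kinase, by 1.40 ± 0.30 and POLR2C, a subunit of RNA polymerase II, by 1.06 ± 0.22. CDC73 and ELL2, which act in elongation, and TAF1 and GTF2E2, which act in initiation, fell, with log2 changes of -1.35, -1.16, -0.95 and -1.16. The list lost its call without untreated replicate 2 (adjusted p = 0.114) or 8 h replicate 1 (adjusted p = 0.163), and with a filter of at least 1 count (adjusted p = 0.0518). Of 8 blood cell markers tested, 2 rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.0122, and adjusted p = 0.632 with an estimated correlation). CD14, a monocyte receptor, went from 14.8 ± 11.3 to 130 ± 28.5 scaled counts. CD79A, of the B-cell receptor, had 0 reads in both untreated libraries and 24 in total at 8 h, at least 8.08-fold higher with a floor of 3 counts over the untreated group.

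The lists whose test did not pass at 8 h held changed genes as well. Of 30 apoptosis regulators 3 rose and 3 fell (3 and 3 adjusted over the list alone, 5 and 7 with the block; list adjusted p = 0.8). PMAIP1 rose by 2.93 ± 0.28, BCL2L11, the BIM gene, by 2.21 ± 0.38 and CYCS, cytochrome c, by 1.03, while CASP8, APAF1 and BCL2 fell, with log2 changes of -1.36, -1.39 and -2.27. Of 27 p53 target genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, 8 and 1 with the block), with a list adjusted p of 0.0876, which was 0.00362 without 8 h replicate 2. These were AEN (1.60 ± 0.24), BTG2 (1.68 ± 0.40), TRIAP1 (1.06 ± 0.28) and GADD45A (0.90 ± 0.25). Of 28 nucleotide excision repair genes 1 rose and 2 fell (0 and 2 adjusted over the list alone, 5 and 4 with the block): RPA3 at 0.87 ± 0.27, and ERCC6, of transcription-coupled repair, at -1.45 ± 0.35 and GTF2H2 at -1.06 ± 0.27. Among 18 NF-kB and cytokine genes NFKBIZ and NFKBIA rose and NFKB1 and TNIP1 fell, with log2 changes of 1.62, 1.10, -1.53 and -0.93. Of 37 splicing regulators CLK1, a kinase of splicing factors, rose by 1.68 ± 0.28 (1 and 0 adjusted over the list alone, 14 up and 1 down with the block). That list had an adjusted p of 0.0582, and 0.0325 without untreated replicate 1, 0.00616 without 8 h replicate 2 and 0.0440 with a filter of at least 50 counts in 2 libraries. Of 28 unfolded protein and stress response genes 4 rose and 1 fell (1 and 1 adjusted over the list alone, 11 and 4 with the block). Of the remaining lists, the changed genes were IRF7 (1.93) and IFIH1 (-1.61) among 29 interferon-stimulated genes (6 up and 8 down with the block). THBS1 (0.81) and ITGA2 (-1.37) were the changed ones of 32 matrix and adhesion genes (5 and 4 with the block). HBEGF and IGFBP3 (1.31 and 0.86) changed of 20 metalloproteinase and senescence-secreted genes (4 and 1 with the block), and OCLN (-1.06) of 7 epithelial markers. Adjusted over the list alone, these counts were 2 and 2 for NF-kB, 1 and 1 for interferon, 1 and 1 for matrix, 2 and 0 for secreted and 0 and 1 for epithelial genes. None of 15 heat shock genes and none of 29 cholesterol and lipid genes passed edgeR's test at 8 h (6 and 0, and 3 and 7, with the block; 0 adjusted over the list alone).

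The largest rises at 8 h were in genes with few reads in untreated cells. AX746690, an mRNA record without coordinates in the annotation, rose by 5.67 ± 0.54 (adjusted p = 0.00109), PYGM, the muscle glycogen phosphorylase, by 5.39 ± 0.66, C1orf116 by 4.73 ± 0.55 and OVGP1, an oviduct glycoprotein, by 4.29 ± 0.55. LOC100128288, TIPARP-AS1, LOC653160, LAMB2P1 and LSMEM1 rose by between 4.38 and 5.62. For LEFTY1, of the TGF-beta family, and LRRN4, untreated cells gave 2 reads in total and the 8 h cells 97, a ratio of 49.0 (95% counting interval 13.2 to 410). For NAALADL1 they gave 3 and 107, a ratio of 36.0 (12 to 178). Some of these genes lie close to expressed genes. TIPARP-AS1 overlaps TIPARP on the other strand and LSMEM1 overlaps IFRD1 on its own strand, NAALADL1 overlaps SAC3D1, and LAMB2P1 is a pseudogene with reads that may belong to its parent gene. Expressed genes end upstream on the same strand at 1684 bp from LAMB2P1 (CCDC71), 4632 bp from PYGM (SF1) and 7747 bp from NAALADL1 (CDCA5).

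The largest falls at 8 h were in MBD5 (-4.63 ± 0.74, adjusted p = 0.00257), PDE7B (-4.48 ± 0.64), TMCC1 (-4.46 ± 0.66), FGD4, an exchange factor of the GTPase CDC42 (-4.44 ± 0.55), NHS (-4.23 ± 0.63) and TMEM178B (-4.17 ± 0.44). FAM110B, ZNF608, GPR39, RARB (the retinoic acid receptor beta), ARHGAP42 and ZNF804A changed by between -4.13 and -3.94. Some had few reads in the 8 h libraries, for instance MBD5 1 and 6, TMCC1 2 and 4 and FAM110B 2 and 6, so the size of these changes is uncertain. FGD4 lies on chromosome 12 at 32552492 to 32798984, RARB on chromosome 3 at 24729378 to 25639423 and ZNF608 on chromosome 5 at 123972606 to 124084500 (GRCh37). FGD4 went from 176 ± 1.76 to 8.06 ± 4.0 scaled counts and ZNF804A from 1792 ± 264 to 116 ± 10.8. MBD5 overlaps ORC4 and GPR39 overlaps LYPD1 on the other strand. In edgeR's test all 24 named genes stayed past the threshold when any of the 4 libraries compared was left out.

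Change at 8 h followed the genomic span of the gene. Spearman's rank correlation across 12867 genes was -0.63, and in the 4 pairs of single libraries it lay between -0.62 and -0.47 (mean -0.58, SD 0.0721). The median log2 fold change was 0.61 in 2564 genes under 10 kb, 0.36 in 3571 genes of 10 to 30 kb, -0.21 in 4176 genes of 30 to 100 kb and -0.98 in 2556 genes over 100 kb. Of genes under 10 kb, 512 rose and 15 fell (46.3% and 2.03% with the block), and of genes over 100 kb 23 rose and 1150, or 45.0%, fell (2.43% and 58.8% with the block). Libraries of one group also differed by span, with a rank correlation of -0.28, -0.13 and -0.49 for replicate 2 against replicate 1 in untreated, 8 h and 24 h cells.

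**Figure D1:**
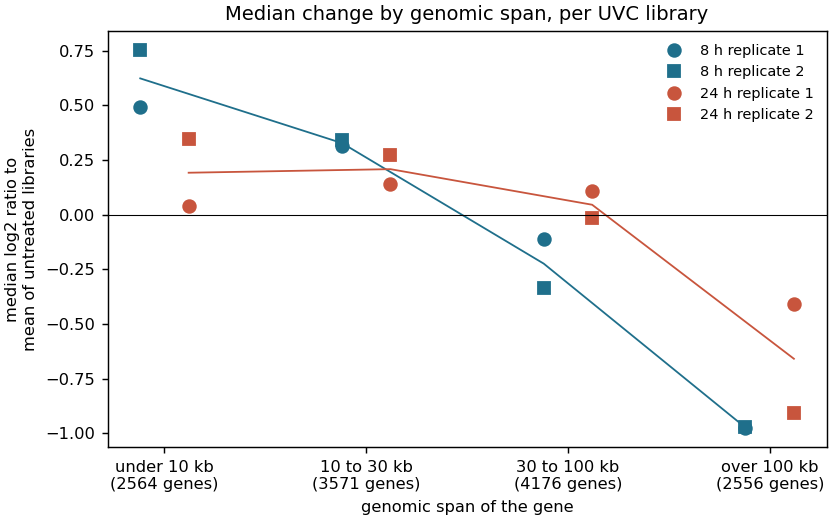
Median log2 ratio (vertical axis) of each UVC library to the mean of the untreated libraries, in 4 bins of genomic span (horizontal axis); circles are replicate 1, squares replicate 2 and lines the mean of both. In genes over 100 kb the 8 h libraries lie at -0.98 and -0.97 and the 24 h libraries at -0.41 and -0.91.

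The second comparison asked which transcripts differed after 24 h of recovery. IFIT2, an interferon-induced antiviral gene, rose from 112 ± 38.2 to 1976 ± 446 scaled counts (SD, n = 2), and CDKN1A, the p21 inhibitor of the cell cycle, from 740 ± 0.534 to 2825 ± 716. COL1A1, a chain of type I collagen, fell from 94632 ± 20425 to 25806 ± 369. In edgeR's test 1112 genes changed, of which 289 rose and 823 fell, 274 and 765 of them by at least 2-fold. With the replicate block 2906 genes changed (1156 rose, 1750 fell), and these held all 1112. Without 24 h replicate 2 the count was 214. Scaling by total counts called 1044, of which 36.6% rose against 26.0% with TMM, with a median over all genes of 0.16 against 0.03.

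Among the 27 p53 target genes, 12 rose and 0 fell at 24 h (17 and 0 adjusted over the list alone, 19 and 0 with the block; adjusted p = 1.07e-10, and adjusted p = 0.331 with an estimated correlation). AEN, a nuclease of apoptotic cells, rose by 2.20 ± 0.25, BTG2 by 3.29 ± 0.42, GADD45A by 1.83 ± 0.25 and CDKN1A by 1.93 ± 0.30. Interferon-stimulated genes rose with them, 9 of 29 with 0 falling (13 and 0 adjusted over the list alone, 15 and 0 with the block; adjusted p = 3.24e-09, and adjusted p = 0.331 with an estimated correlation). IFIT2 rose by 4.14 ± 0.45, IFIT3 by 3.15 ± 0.47, OASL by 3.74 ± 0.57 and DDX58, the RIG-I sensor of viral RNA, by 2.46 ± 0.38. IFIT2 overlaps LIPA on the other strand. Of 18 NF-kB and cytokine genes TNFAIP3, NFKB2 and RELB rose, by 1.63 ± 0.36, 1.49 ± 0.34 and 2.14 ± 0.51, and 0 fell (6 and 1 adjusted over the list alone, 7 and 1 with the block; adjusted p = 3.61e-04, and adjusted p = 0.331 with an estimated correlation). Of the 32 immediate early genes 9 rose and 1 fell (12 and 2 adjusted over the list alone, 13 and 2 with the block; adjusted p = 1.95e-04, and adjusted p = 0.369 with an estimated correlation). ATF3 was 2.66 ± 0.27 and KLF4, a transcription factor, 2.52 ± 0.34 above untreated, and CYR61 changed by -1.44. Of 16 histone genes 2 rose, HIST1H3A by 2.18 ± 0.33 and HIST1H2BO by 2.35 ± 0.55 (7 and 0 adjusted over the list alone, 5 and 0 with the block; adjusted p = 5.97e-07, and adjusted p = 0.331 with an estimated correlation). The share of RNA5-8S5 was also higher than in the untreated library of the same number, 0.595% against 0.481% and 1.48% against 1.22%. Of 30 apoptosis regulators PMAIP1, BBC3 (the PUMA gene), BMF and BCL2L11 rose, the first 3 by 2.22 ± 0.27, 2.73 ± 0.43 and 2.46 ± 0.51, and 0 fell (5 and 0 adjusted over the list alone, 6 and 2 with the block; adjusted p = 0.00519, and adjusted p = 0.371 with an estimated correlation).

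Matrix genes fell at 24 h: 19 of 32 were lower and 0 higher (22 and 0 adjusted over the list alone; adjusted p = 2.92e-11, and adjusted p = 0.331 with an estimated correlation), and their median span was 86.0 kb. FBN2, a fibrillin, changed by -2.56 ± 0.26, COL1A1 by -1.87 ± 0.21 and COL5A1 by -2.24 ± 0.28. Of 29 genes of cholesterol and lipid synthesis 11 fell and 0 rose (14 and 0 adjusted over the list alone, 20 and 0 with the block; adjusted p = 5.45e-07, and adjusted p = 0.369 with an estimated correlation), among them ACACA, acetyl-CoA carboxylase, at -2.24 ± 0.37, SCD, a fatty acid desaturase, at -1.77 ± 0.30 and FASN, fatty acid synthase, at -1.33 ± 0.25. Of 15 heat shock genes HSPA8, HSP90AB1 and HSPA1A fell, with changes of -0.99 ± 0.12, -0.70 ± 0.15 and -1.20 ± 0.32 (4 and 0 adjusted over the list alone, 9 and 0 with the block; adjusted p = 0.0194, and adjusted p = 0.371 with an estimated correlation). The heat shock list lost its call without any 1 of the 4 libraries (untreated replicate 1, adjusted p = 0.0929; untreated replicate 2, 0.0698; 24 h replicate 1, 0.0685; 24 h replicate 2, 0.0891).

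General transcription genes passed as a list with HEXIM1 (1.36 ± 0.24) and POLR2A (0.92 ± 0.22) the 2 members that rose (2 and 0 adjusted over the list alone, 9 and 0 with the block; adjusted p = 0.0105, and adjusted p = 0.371 with an estimated correlation). They did not without untreated replicate 2 (adjusted p = 0.0698). The G2/M list was at its threshold (adjusted p = 0.0498, and adjusted p = 0.760 with an estimated correlation) with 0 of 41 members changed (0 adjusted over the list alone, 5 up with the block). It lost its call without untreated replicate 2 (0.634) or 24 h replicate 1 (0.694) and with DESeq2 size factors (0.0583), a filter of at least 1 count (0.0752) or a fit of the 4 libraries compared (0.0512). Of 8 blood markers CD14 rose by 2.43 ± 0.56, and CD79A, with 0 reads in untreated cells and 30 at 24 h, was at least 8.48-fold higher (2 and 0 adjusted over the list alone; adjusted p = 0.0377, and adjusted p = 0.369 with an estimated correlation). The blood marker list did not pass with the replicate block (adjusted p = 0.0656), with total count scaling (0.0652), with a filter of at least 1 count (0.0933), without untreated replicate 1 (0.0598) or without 24 h replicate 2 (0.118). In the unfolded protein and stress response list, which did not pass, DDIT3, the CHOP transcription factor, SESN2 and CHAC1 rose by 2.47 ± 0.32, 1.49 ± 0.31 and 1.84, and the chaperones HSPA5, HSP90B1 and PDIA4 changed by -0.79, -0.84 and -0.79 (4 up and 6 down adjusted over the list alone, 6 and 6 with the block). Among metalloproteinase and secreted genes GDF15 and AREG rose by 2.65 ± 0.56 and 1.39 ± 0.32, and IGFBP5, which binds insulin-like growth factors, was 1 of 2 that fell, with a change of -1.66 ± 0.41 (2 and 5 adjusted over the list alone, 2 and 6 with the block). DDB2, a sensor of UVC lesions, was the 1 changed repair gene at 1.00 ± 0.28 (adjusted p = 0.0498; 0 adjusted over the list alone, 3 up and 1 down with the block). POLA1 was the 1 changed G1/S gene at -1.04 ± 0.27 (0 adjusted over the list alone, 2 and 6 with the block), and NDUFS4 the 1 changed oxidative phosphorylation gene at -1.35 ± 0.29 (1 adjusted over the list alone, 2 with the block). In edgeR's test 0 ribosomal protein, 0 splicing regulator and 0 epithelial genes passed at 24 h, over all genes or adjusted over the list alone (1 up and 4 down, 5 and 6, and 0 with the block).

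**Figure D2:**
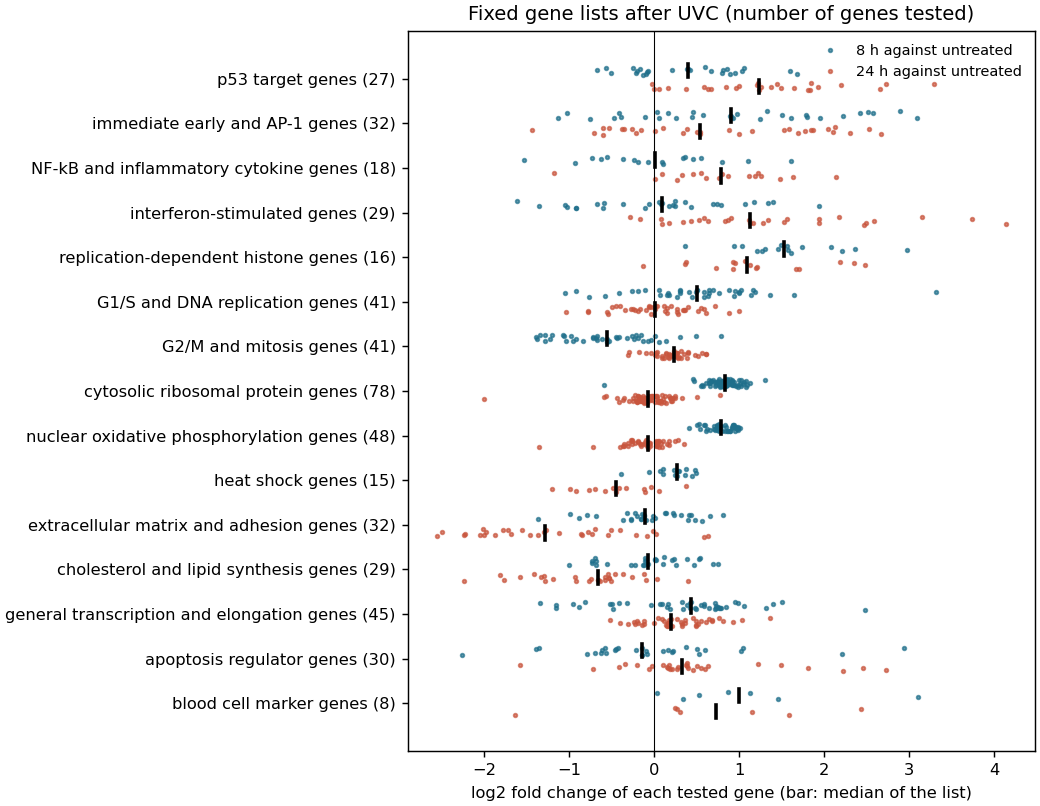
Log2 fold change (horizontal axis) of each tested gene of the lists that passed in any comparison, at 8 h and at 24 h against untreated; black bars are list medians. Ribosomal protein genes have a median of 0.83 at 8 h and -0.08 at 24 h, matrix genes -0.11 and -1.28. CD79A, with 0 untreated reads, is not drawn.

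OVGP1 had the largest rise at 24 h, 4.61 ± 0.54 (adjusted p = 0.00127), followed by IFIT2, PYGM (4.09 ± 0.65), RRAD, a small GTPase (3.96 ± 0.78), and C1orf116 (3.80 ± 0.54). TINAGL1, OASL, LSMEM1, CCRL2 (a chemokine receptor-like protein), KCNK3 (a potassium channel) and AGXT2L1 rose by between 3.29 and 3.78. RRAD starts 6530 bp beyond FAM96B. For TMEM117 the 24 h cells gave 2 reads in total and untreated cells 97, a ratio of 57.2 (95% counting interval 15.4 to 479). GRIN2A, a subunit of the NMDA receptor, changed by -5.65 ± 0.64, MBD5 by -5.11 ± 0.76 and LARGE, a glycosyltransferase, by -5.02 ± 0.90. ATG10, the cadherins CDH18 and CDH12, FOXP2, PRKG1 (a cyclic GMP-dependent kinase), WDR17, KCNQ5 and LDB2 changed by between -4.96 and -3.98. Some of them had few reads in the 24 h libraries: MBD5 1 and 5, LARGE 4 and 0, ATG10 0 and 5. FOXP2 had 1 and 4, WDR17 4 and 4 and KCNQ5 0 and 7, so the size of these changes is uncertain. Spans of the 12 fallen genes ran from 117 to 1308 kb. ATG10 overlaps RPS23 and PRKG1 overlaps CSTF2T on the other strand. Without 24 h replicate 2, 16 of the 24 genes kept their call, and RRAD, TINAGL1, LSMEM1, KCNK3, AGXT2L1, LARGE, WDR17 and KCNQ5 lost it. KCNK3 also lost it without untreated replicate 1, and KCNK3, AGXT2L1 and KCNQ5 without 24 h replicate 1.

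Long genes were lower at 24 h as well. The rank correlation across genes between change and span was -0.41, and -0.22 without 24 h replicate 2. It lay between -0.55 and -0.13 in the 4 pairs of single libraries (mean -0.37, SD 0.179), so that the spread between pairs was wider than at 8 h. Genes over 100 kb had a median of -0.65, with 640 called lower and 6 higher (41.6% and 1.02% with the block), and genes under 10 kb a median of 0.17.

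Genes that rose at both times numbered 159 of 1161 at 8 h and 289 at 24 h, and 306 fell at both, of 1748 and 823, where independent lists of these sizes would share 23.7 and 102. With the block the genes changed the same way at both times were 1402 against 465 without it. In 20 draws with all libraries simulated and no gene changed, the comparisons at 8 h and 24 h shared 0 calls. With no gene changed, few calls are expected in either comparison. That count therefore cannot show how much the shared untreated libraries add to the overlap. The log2 fold changes at 8 h and 24 h correlated across genes with r of 0.54 against a simulated mean of 0.51. Their covariance was 0.488 against 0.0975, a difference of 0.391. With 1 untreated library for each comparison, so that none was shared, 271 genes changed the same way at both times, against 72.3 for independent lists, and with the libraries exchanged 308 against 66.0. The correlation was then 0.36 and 0.41.

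The third comparison tested the 2 recovery times against each other. FGD4, ZNF608 and RARB, low at 8 h, were higher again at 24 h, by 3.32, 3.80 and 3.06, with 81.7, 165 and 323 scaled counts on average. The cadherin genes CDH12 and CDH4, GMDS, an enzyme of fucose synthesis, and HSPG2, the proteoglycan perlecan, were lower at 24 h than at 8 h by between -4.17 and -3.23. GMDS had 436 ± 20.3 scaled counts untreated, 484 ± 11.5 at 8 h and 49.7 ± 15.0 at 24 h (SD, n = 2). In edgeR's test 2850 genes differed, 1535 higher and 1315 lower at 24 h, 1374 and 918 of them by at least 2-fold. With the block 5928 differed (2912 higher, 3016 lower), and these held all 2850. Without 24 h replicate 1 the count was 558, without 8 h replicate 2 1471 and without 24 h replicate 2 1552. With total count scaling 3437 differed, 82.0% of them higher against 53.9% with TMM, and the median over all genes was 0.28 against -0.04.

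Higher at 24 h than at 8 h were 20 of 41 mitotic genes and 0 lower (25 and 0 adjusted over the list alone, 32 and 1 with the block; adjusted p = 5.6e-07, and adjusted p = 0.485 with an estimated correlation), for instance BUB1B at 1.40 ± 0.25 and TTK, a spindle checkpoint kinase, at 1.84 ± 0.37. Interferon-stimulated genes were higher for 12 of 29 and lower for IFITM3 at -0.85 (16 and 2 adjusted over the list alone, 17 and 2 with the block; adjusted p = 2.96e-05, and adjusted p = 0.420 with an estimated correlation), with DDX58 at 3.49 ± 0.40 and DDX60 at 3.64 ± 0.51. Of 27 p53 targets 8 were higher and 0 lower (11 and 0 adjusted over the list alone, 16 and 0 with the block; adjusted p = 2.2e-05, and adjusted p = 0.420 with an estimated correlation), with BBC3 at 2.95 ± 0.43 and FAS, a death receptor, at 2.38 ± 0.57. NF-kB and cytokine genes had 7 higher, such as NFKB1 at 1.80 ± 0.32 and RELB at 2.69 ± 0.52, and NFKBIZ and NFKBIA, both inhibitor-like members, lower at -1.16 and -1.01 (7 and 2 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.420 with an estimated correlation). Of apoptosis regulators 9 of 30 were higher and 0 lower, APAF1 at 1.78 ± 0.34 and CASP8 at 1.51 ± 0.31 among them (11 and 2 adjusted over the list alone, 12 and 3 with the block; adjusted p = 0.0132, and adjusted p = 0.512 with an estimated correlation). Without 8 h replicate 2 it lost its call (0.112).

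Lower at 24 h than at 8 h were 55 of 78 ribosomal protein genes and 0 higher (70 and 0 adjusted over the list alone; adjusted p = 6.48e-16, and adjusted p = 0.420 with an estimated correlation), with RPL15 at -1.03 ± 0.16. Of oxidative phosphorylation genes 25 of 48 were lower and 0 higher (37 and 0 adjusted over the list alone, 46 and 0 with the block; adjusted p = 2.69e-11, and adjusted p = 0.420 with an estimated correlation), with NDUFS4 at -1.85 ± 0.29. Matrix genes were lower for 21 of 32 and higher for 0 (23 and 0 adjusted over the list alone, 25 lower and 3 higher with the block; adjusted p = 1.76e-08, and adjusted p = 0.420 with an estimated correlation), FBN2 at -2.24 ± 0.25. Lipid genes were lower for 12 of 29 and higher for 0 (12 and 0 adjusted over the list alone, 21 and 1 with the block; adjusted p = 3.07e-05, and adjusted p = 0.420 with an estimated correlation), SCD at -1.87 ± 0.31. G1/S genes were lower for 9 of 41 and higher for 0 (11 and 1 adjusted over the list alone, 22 and 1 with the block; adjusted p = 0.00259, and adjusted p = 0.541 with an estimated correlation), CCNE1 at -2.74 ± 0.32 and PCNA at -1.25 ± 0.21. Without 8 h replicate 1 this list lost its call (0.0721). Heat shock genes were lower for 7 of 15 and higher for 0 (10 and 1 adjusted over the list alone, 11 and 1 with the block; adjusted p = 0.00433, and adjusted p = 0.420 with an estimated correlation), HSPA8 at -1.36 ± 0.13. Lists that did not pass had 0 up and 2 down for immediate early genes (0 and 1 adjusted over the list alone, 4 and 7 with the block), 2 and 2 for repair genes (2 and 2 adjusted over the list alone, 10 and 8 with the block), 0 and 3 for histones (0 adjusted over the list alone), and 2 and 5 for stress response genes (2 and 6 adjusted over the list alone, 6 and 10 with the block). They had 2 and 5 for secreted genes (3 and 8 adjusted over the list alone, 3 and 9 with the block), 0 and 5 for splicing regulators (0 and 5 adjusted over the list alone, 5 and 15 with the block), 3 and 4 for general transcription genes (3 and 4 adjusted over the list alone, 10 and 13 with the block), 1 and 0 for epithelial markers (1 and 0 adjusted over the list alone) and 0 for blood markers (0 adjusted over the list alone, 1 down with the block). No call of a list in the 3 comparisons holds with an estimated correlation, and fry passed 3, 2 and 3 lists. The histone list passed without 24 h replicate 2 (0.0231) and with a filter of at least 50 counts (0.0204), the secreted list without 24 h replicate 1 (0.0409) and the splicing regulators without 8 h replicate 2 (0.0170).

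For KCNK3 the 8 h cells gave 3 reads in total and the 24 h cells 130, a ratio of 36.4 (95% counting interval 12.2 to 179). AGXT2L1, LIPH, a lipase, ZNF608 and DDX60, an interferon-induced helicase, were higher at 24 h than at 8 h by 4.84 ± 0.79, 4.81 ± 0.78, 3.80 ± 0.53 and 3.64 ± 0.51. The 8 h libraries held 1 and 4 reads of AGXT2L1 and 2 and 2 of LIPH, so the size of these 2 changes is uncertain. CDH12 (-4.17 ± 0.44), LOC284080 (-3.50 ± 0.70), CDH4 (-3.34 ± 0.55), GMDS (-3.27 ± 0.34), CPS1, a urea cycle enzyme (-3.25 ± 0.45), and HSPG2 (-3.23 ± 0.39) were lower. CDH12 lies on chromosome 5 at 21750782 to 22853453, GMDS on chromosome 6 at 1624041 to 2245839 and HSPG2 on chromosome 1 at 22148737 to 22263803 (GRCh37). HSPG2 overlaps LDLRAD2 on the other strand. LOC284080, which has no coordinates in the annotation, lost its call without either 24 h library. Genes over 100 kb went both ways between the times, 25.7% higher and 14.6% lower (37.2% and 20.7% with the block), and the rank correlation across genes with span was 0.28 (0.09 to 0.36 in pairs of single libraries).

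**Figure D3:**
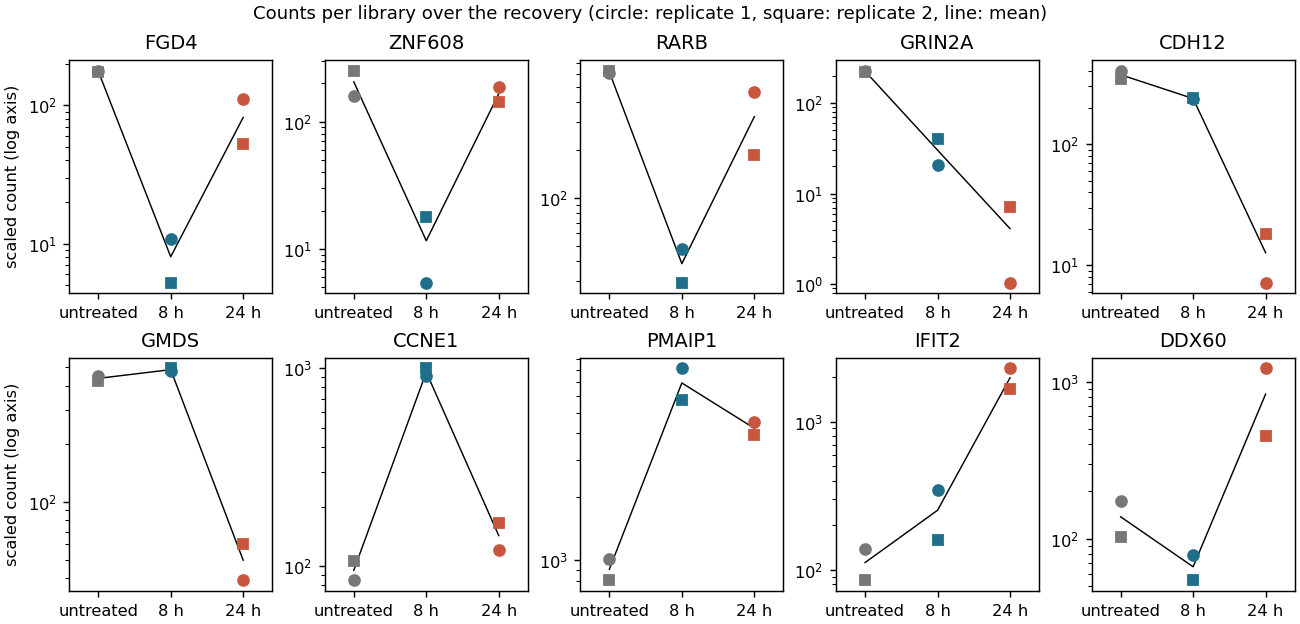
Scaled counts of 10 genes (vertical log axis) in each library over the recovery (horizontal axis); circles are replicate 1, squares replicate 2 and lines the group means. CCNE1 has group means of 95.4, 953 and 143 and GMDS of 436, 484 and 49.7, untreated, at 8 h and at 24 h.

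Splicing was compared in each UVC library against its reference. At 8 h, 134 events changed in both replicates, 122 of them on primary chromosomes, and at 24 h 84, with 82 on primary chromosomes. They comprised 41 skipped exons at 8 h and 30 at 24 h, 48 and 28 alternative last exons, 10 and 6 alternative first exons, 11 and 4 retained introns, 11 and 7 alternative 3' splice sites, 7 and 3 alternative 5' splice sites, and 6 and 6 pairs of mutually exclusive exons. Of the skipped exons, 17 gained inclusion and 24 lost it at 8 h, and 6 and 24 at 24 h. Of the retained introns 1 gained and 10 lost retention at 8 h, where 5 of the losses are copies on alternate haplotypes, so that 1 gained and 5 lost on primary chromosomes, and 2 and 2 at 24 h. The 11 alternative 3' splice sites at 8 h likewise come to 5 on primary chromosomes. Requiring both replicates mattered, since 985 events passed at 8 h without replicate 2 and 488 without replicate 1, and 1213 and 388 at 24 h.

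USMG5, a subunit of ATP synthase, had its exon on chromosome 10 at 105155503 to 105155789 included in 0.93 and 0.92 of transcripts in the reference and 0.47 and 0.32 at 8 h in the authors' deposited table. BOD1L1 included its exon on chromosome 4 at 13625014 to 13627936 in 0.10 and 0.11 of transcripts before and 0.57 and 0.70 at 8 h in the authors' deposited table. TBX3, a transcription factor, went from 0.65 and 0.52 to 0.10 and 0.08 for its exon on chromosome 12 at 115117718 to 115117777 in the authors' deposited table. The top skipped exons at 24 h were in FAM64A, CCDC14 and CLSTN1, with lower inclusion, and in IVNS1ABP, with higher inclusion and a mean change as large as that of CLSTN1. CLSTN1 went from 0.63 and 0.73 to 0.24 and 0.32 in the authors' deposited table. An intron of POLR2G, of RNA polymerase II, went from 0.63 and 0.43 to 0.17 and 0.13 retained at 8 h, and one of C1orf63 from 0.92 and 0.64 to 0.42 and 0.25 at 24 h, in the authors' deposited table. Other retained introns with the largest change were in TSPAN31 (gained) and WRAP73 (lost) at 8 h and in RPL31 and HCFC1R1 (both gained) at 24 h. Splice site changes were led by TCF19, ACAA1, MIR22HG and NABP1 at 8 h and by RPL22L1, C1orf63, SCAF11, TRIM24 and SDC2 at 24 h, and mutually exclusive exons by USMG5, RPAIN and NHP2L1, and by DMTF1 and NIPA2. Alternative first exons were led by PIGA and VEZT at 8 h and by CUL7, CCPG1 and DNHD1 at 24 h.

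At 8 h 32 of 48 alternative last exon events moved to the promoter-proximal last exon (66.7%, 95% Clopper-Pearson interval 51.6 to 79.6, exact binomial p = 0.0293 across events). That did not hold by gene (24 of 37, exact p = 0.0989) or over all events listed in both replicates (99 proximal and 93 distal, exact p = 0.718), and was 53.3% with a change of at least 0.3. At 24 h 23 moved to the proximal and 4 to the distal exon (85.2%, interval 66.3 to 95.8, exact p = 3.11e-04), and by gene 18 and 3 (exact p = 0.00149). Without replicate 2 the share at 24 h was 52.8%, and at 8 h 51.7%. The 6 events that passed at both times moved the same way. ZEB2, a transcription factor, used its proximal last exon in 0.05 and 0.07 of transcripts before and 0.46 and 0.56 at 8 h in the authors' deposited table. MARK1 moved to its proximal and SLC26A1 to its distal last exon at 8 h, and CDKAL1, CRYZL1 and CNTLN to their proximal ones at 24 h. CDKAL1 carried the distal exon in 0.91 and 0.95 of transcripts in the reference and in 0.36 and 0.18 at 24 h in the authors' deposited table. For alternative first exons 5 events moved to the upstream and 4 to the downstream exon at 8 h (exact p = 1), and 1 and 4 at 24 h (exact p = 0.375).

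ASCC3, a helicase subunit of the ASCC complex, lies on the minus strand of chromosome 6 at 100956070 to 101329248 (GRCh37), and its use of a short isoform after UVC is what the study is known for. Its proximal last exon is at 101304179 to 101307078 and its distal one at 100956608 to 100957409, with another between them at 101295880 to 101296583 (hg19). Against the distal exon, the proximal one was used in 0.21 and 0.18 of transcripts in the reference and in 0.51 and 0.60 at 24 h in the authors' deposited table. Against the middle exon, its share went from 0.25 and 0.33 to 0.67 and 0.65 in the authors' deposited table. At 8 h a shift among ASCC3 last exons was listed for replicate 1 alone, between the middle and distal exons. It went to the distal exon, from 0.55 to 0.69 in the authors' deposited table, and its change of 0.14 lies below the minimum of 0.2. That pair leaves out the proximal exon, so its direction cannot be set against the gain of the proximal exon at 24 h. Gene counts of ASCC3 averaged 3049 ± 792 scaled counts untreated, 1566 ± 123 at 8 h and 1429 ± 721 at 24 h (SD, n = 2). Its log2 changes of -0.96 ± 0.36 at 8 h and -1.09 ± 0.36 at 24 h did not pass edgeR's test (adjusted p = 0.0770 and 0.0935), and did with the replicate block (adjusted p = 0.0103 and 0.00869). Between the times it differed by -0.13 ± 0.35 (adjusted p = 0.811).

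**Figure D4:**
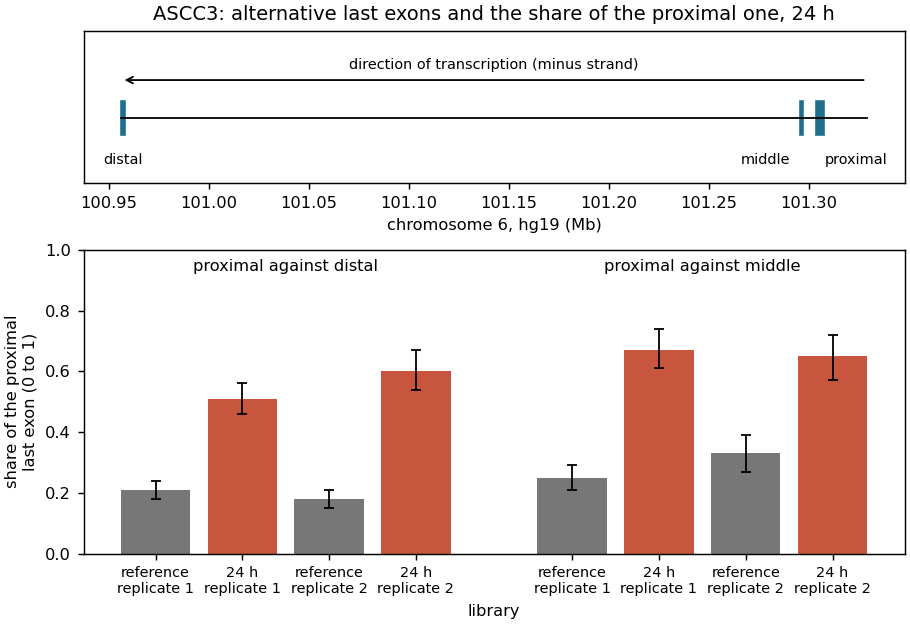
Top, map of ASCC3 on chromosome 6 with its 3 alternative last exons drawn to scale in Mb. Bottom, share of the proximal last exon (0 to 1) in each reference and 24 h library, with bars for the authors' MISO means and error bars for their intervals; the 24 h bars lie between 0.51 and 0.67 and the reference bars between 0.18 and 0.33.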

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

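The test of 24 h against 8 h was chosen before the data were examined, and it set apart 2850 genes, 11 lists and, among the genes named for the size of their change, 15 that were higher and 15 that were lower at 24 h (adjusted p from 0.00171 to 0.0320). None of the 11 lists passes with an estimated correlation, and 3 lists pass with fry. A change at one time is thus not read as a change at the other for these genes.

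Median log2 changes from 8 h to 24 h were 0.71 for p53 targets, 0.86 for NF-kB and cytokine genes, 1.26 for interferon-stimulated genes, 0.76 for mitotic genes and 0.45 for apoptosis regulators. They were -0.37 for G1/S genes, -0.89 for ribosomal protein genes, -0.93 for oxidative phosphorylation genes, -0.79 for heat shock genes, -1.12 for matrix genes and -0.70 for lipid synthesis genes. Ribosomal protein genes had a median of 0.83 at 8 h, where 43 of 78 rose, and of -0.08 at 24 h. All tested genes under 10 kb had medians of 0.61 at 8 h, 0.17 at 24 h and -0.44 from 8 h to 24 h. The list test does not separate the ribosomal and oxidative phosphorylation lists from other short genes. From 8 h to 24 h the G1/S median lay within the quartiles of all genes of 10 to 30 kb (-0.56 and 0.30). The mitotic median lay within those of 30 to 100 kb (-0.28 and 0.79), so the test does not separate these from genes of like span. The matrix and lipid lists passed at 24 h and not at 8 h. With an estimated correlation the adjusted p was 0.632 for ribosomal genes at 8 h, and 0.331 and 0.369 for matrix and lipid genes at 24 h.

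Of the genes named for their fall at 8 h, those higher at 24 h than at 8 h were FGD4 (3.32), NHS (2.12), FAM110B (2.99), ZNF608 (3.80), RARB (3.06), ARHGAP42 (2.36) and ZNF804A (2.91). IFIT2 (2.97), TINAGL1 (2.92), OASL (3.49), CCRL2 (3.41), KCNK3 (fitted 5.11, from 3 reads at 8 h), AGXT2L1 (4.84), LIPH (4.81) and DDX60 (3.64) were also higher. Of the genes risen at 8 h, AX746690 (-2.60), TIPARP-AS1 (-2.40) and LOC653160 (-2.26) were lower again. TMEM117 (fitted -4.22, from 2 reads at 24 h), GRIN2A (-2.76), LARGE (-3.81), CDH18 (-2.54), CDH12 (-4.17), PRKG1 (-2.87), WDR17 (-2.93), LOC284080 (-3.50), CDH4 (-3.34), GMDS (-3.27), CPS1 (-3.25) and HSPG2 (-3.23) were lower as well.

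The tests of the patterns weighed here and under the other observations were chosen after the main results had been seen. The first pattern is the fall of long genes at 8 h. Rank correlation across genes between change and span was -0.488 (interval -0.501 to -0.474) once exonic length, GC content and expression level were held fixed, which argues against these as the whole cause. It was -0.437 (-0.450 to -0.422) once the differences between replicates were regressed out, against -0.632 before. Both intervals come from 200 resamplings of genes and not of libraries. Each difference rests on 1 pair of libraries, so regression may remove only a part of a length trend between replicates, which is not excluded. In 3 equal groups of genes by expression the rank correlation was -0.549, -0.712 and -0.692. Lesions that stop the polymerase in proportion to the length transcribed would need a negative value in each. That remains a hypothesis, since it was found and tested on the same data, and slower turnover of short transcripts was not tested.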

How the results depend on the processing

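All alternatives here were planned except the count of splicing events on primary chromosomes and the split of the untreated libraries, chosen after the data had been seen. With the replicate block the changed genes were 5988 at 8 h, 2906 at 24 h and 5928 between the times, and 1402 changed the same way at 8 h and 24 h. With 1 untreated library for each comparison these were 271 or 308, with fewer libraries in each. Of 31 list calls the block ended that of blood markers at 24 h, and it changed no other call of a list. All 229 calls of named genes and list members were kept with it and 47 were added. No list call and no call of a named gene turned its direction under the alternatives run. Of the lists that did not pass, NF-kB genes at 8 h turned with the block, and G1/S genes at 24 h with the block and with fry. An adjusted p under 0.01 left 1051, 421 and 786 genes. Leaving out 1 library gave 1566 to 2797 genes at 8 h, 214 to 1116 at 24 h and 558 to 3276 between the times.

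With an estimated correlation 0, 0 and 0 lists passed, and with fry 3, 2 and 3. The rank correlation of change with genomic span was -0.63 to -0.54 at 8 h and -0.52 to -0.22 at 24 h with 1 library left out, and with exonic length in place of span -0.42 and -0.23.

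Splicing events numbered 43 at 8 h and 35 at 24 h when a change of at least 0.3 was required, and 488 to 985 and 388 to 1213 from 1 replicate alone. The share of last exon events that moved to the proximal exon was 53.3% at 8 h with a change of at least 0.3. From 1 replicate alone it was 51.7% to 59.5% at 8 h and 52.8% to 87.7% at 24 h. First exon events at 8 h moved to the upstream exon in 55.6% of cases from both replicates, in 66.7% with a Bayes factor of at least 100, and in 43.3% and 46.6% without replicate 1 and 2. First exon events at 24 h moved to the upstream exon in 27.6% to 64.0% of cases from 1 replicate alone, and the higher value, without replicate 2, is the opposite direction to that from both. The cause of these differences was not tested, beyond the fewer libraries or events in each.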

Other observations

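The grouping of long genes by span and the tests in this part were chosen after the main results had been seen. Of all genes of 100 to 200 kb, 30.3% were higher at 24 h than at 8 h and 8.71% lower, of those of 200 to 400 kb 22.4% and 19.5%, and of those over 400 kb 9.29% and 33.0%. Among genes chosen for a fall at 8 h, whose 8 h libraries enter both tests, the shares that were higher again were larger. Of the genes of 100 to 200 kb that had fallen at 8 h, 427 of 687 (62.2%) were higher at 24 h than at 8 h, of those of 200 to 400 kb 147 of 331 (44.4%), and of those over 400 kb 27 of 132 (20.5%). In the last group 13 were lower still at 24 h. The median log2 change at 8 h was -0.94, -1.10 and -1.07 in these bins of 1562, 682 and 312 genes, and at 24 h -0.37, -1.11 and -2.04. In edgeR's test 3 genes rose at 8 h and fell at 24 h: TAGLN (0.73 and -1.31), TMSB4X (0.63 and -1.06) and VIM (0.55 and -0.63).

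First exons moved downstream at 8 h over the events listed in both replicates with the same sign, whatever the size of their change. In 15 events the upstream first exon gained and in 62 the downstream one, 19.5% upstream (interval 11.3 to 30.1, exact p = 6.08e-08 across events), and by gene 11 and 27 (exact p = 0.0139). At 24 h these were 16 and 34 events (32.0%, 19.5 to 46.7, exact p = 0.0153) and 11 and 12 genes (exact p = 1). With a change of at least 0.2 in both replicates, first exon events at 8 h split into 5 upstream and 4 downstream. For last exons of any size the share moving to the proximal one was 51.6% at 8 h (exact p = 0.718) and 75.7% at 24 h (exact p = 9.37e-08).

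The second pattern weighed is the gain of proximal last exons at 24 h. The median difference between the 2 reference libraries was 0.105 of the shift after UVC (interval 0 to 0.21), but over events chosen for the same sign in both replicates, so that this decides nothing on a length trend between replicates. In replicate 1 alone 130 events moved to the proximal and 116 to the distal exon (52.8%, interval 46.4 to 59.2), and in replicate 2 alone 57 and 8 (87.7%, 77.2 to 94.5), so a difference between replicates stays open. Events with last exons at least 10 kb apart gained the proximal one at an odds ratio of 0.855 (0.297 to 2.33) to closer ones, so that loss of far ends may or may not explain the gain. The width of that interval keeps this open as well.

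The third pattern is the rise of little expressed genes at 8 h. Of 125 genes risen at least 4-fold from a low level, 40 had an expressed same-strand gene within 10 kb upstream but not downstream and 11 the reverse, a ratio of 3.636 (exact p = 5.7e-05). An upstream neighbour was found for 41.6% of them and 24.5% of 375 matched genes (odds ratio 2.19, interval 1.39 to 3.43), so reads that run on from it may be a part of the rise. Matched genes lean upstream too, 67 against 31, and the ratio of sides did not differ past the threshold (odds ratio 1.68, 0.722 to 4.12, exact p = 0.25). Overlap with an expressed gene was no more frequent than in matched genes (odds ratio 0.902, 0.557 to 1.44), which argues against shared reads as the whole cause.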
